A study of Homo sapiens with 4 samples.

How the data were processed

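Total RNA of 4 cultures of human embryonic stem cells was extracted with Trizol and amplified to biotin-labelled cRNA for Illumina bead arrays, per the labels. Each culture has 1 array. BeadStudio is named per the submitters' processing notes, and its version, the background method and any normalization between arrays are not given in the sources used here. The deposited signal is a linear probe intensity, already background-subtracted, since 33.0% to 34.5% of the values of an array lie below 0. Sorted signals differ between arrays, so no quantile normalization between arrays was seen in the values. Scaling of an array by a factor would leave them different too, so it cannot be excluded. The deposited detection score is a fraction from 0 to 1 that is high where a probe exceeds the control probes, per the file headers and the values. The deposited value table of the series holds the same intensity values as the array tables (largest difference 0, medians of 5.5, 5.8, 6.1 and 5.6), so its scale is linear, it is not centred, and it adds no independent processing. No bead SD or bead number was in these tables, so the clause of the naming rule that would use them was not applied.

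Signals were quantile-normalized over all probes, values below 0 were set to 0, and differences were taken on log2(signal + 16). That offset understates the change of weakly expressed genes. A probe counted as detected at a score of at least 0.99. Of the 47289 probes, 18468 are in the platform annotation used here, all with 1 gene symbol, and 28821 are not; 18451 were named through it with symbols updated to GRCh38.p14 gene names, 744 through their accession, and 28094 stayed unnamed. Probes of XIST, TSIX and Y-linked genes were left out (40 probes). A gene was represented by its probe with the highest mean signal; 1702 genes had over 1 probe. Where all arrays of the dimmer side were undetected, a fold is given as at least a bound: the bright side's mean on log2(signal + 16), less that of the dim side with each array at the higher of the probe's signal and the array's lowest detected normalized signal. The offset is thus on both sides, which makes the bound smaller than a ratio of the signals. The offset sets the log2 difference of such a gene, so its place in an order by difference depends on the offset. The assembly of the gene table is GRCh38.p14, used for gene names and chromosomes; the submitters' records name no genome build, and no coordinates are given.

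Between 2 arrays, a gene was called higher or lower at a difference of at least 1 log2 unit (2-fold) with detection in the brighter array. For the media, both arrays of the brighter medium had to be detected and to lie at least 1 log2 unit above both arrays of the other. These calls describe the arrays and carry no p-value. A secondary test with limma (lmFit and eBayes with trend, Benjamini-Hochberg adjustment) compared 2 arrays per medium, with residual degrees of freedom of 2. It treats arrays of different lines and passages as replicates of a medium, and its p-values measure only the spread between these arrays. For a gene list, the median difference of its detected members was ranked among 10000 random lists of the same size drawn from 10 bins of mean expression. The 27 lists hold 526 genes, of which 513 were found on the array. For the overlap of p10 and p32, 100 sets of unchanged arrays were simulated against the same control. Their noise was taken from the differences between p32 and p10.

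The named genes were fixed by rule: the 12 higher and 12 lower genes with the largest difference of medium means among those separated by medium, the 8 higher and 8 lower with the largest difference for p32 against p10 and for BG02 against BG03, up to 4 detected members per list with the largest difference by medium, and POU5F1, NANOG, SOX2, LIN28A, DNMT3B and TDGF1. Probes with no symbol or a pseudogene or unnamed-locus symbol were skipped. The text names part of the list members under this rule, and 2 genes among those with the largest differences between the lines are not reported here. Other genes were named after their values were seen: members of the Nodal and activin, BMP, p53 and FGF-ERK lists given beside their list, and the genes named in the additional observations. Of 155 such entries by rule, 8 had another detected probe, and 5 of these had the same sign on all probes.

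The steps were tested on simulated data for the media comparison, on 8263 genes of which 200 were changed. The size rule recovered 16%, 78%, 98% and 100% of genes changed by 1, 1.5, 2 and 3 log2 units, with 0 calls among 8063 unchanged genes, and limma 88%, 100%, 100% and 100%, with 11 such calls. All simulated arrays had noise taken from p32 against p10, the narrowest pair (SD 0.31, against 0.60 between the MEF-CM arrays). Recovery and false calls were thus not tested at the spread between the lines. Of 100 unchanged lists, 4 fell outside the central 95 percent. The number of arrays limits the precision. The design, the lists, the naming rule and the alternatives were chosen before the data were examined. Alternatives were scaling to equal medians of detected probes, the signals as deposited, the value table of the series, an offset of 50, a floor at the detection limit, detection in all 4 arrays, no detection filter, every probe by itself, folds of 1.5 and 3, each array left out in turn, and line as a further term in limma. In that last fit the lone BG03 array is absorbed by its term, so 2 DC-HAIF arrays are set against 1 BG02 array in MEF-CM, the spread comes only from p10 against p32, and the lone array is assumed to vary like them. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 were used.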

Results

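Gene expression was measured in 2 human embryonic stem cell lines, BG02 and BG03, on 1-colour bead arrays with 47289 probes. In 3 cultures the variable was the medium: BG02 cells were kept for 64 passages in MEF-CM, the standard medium conditioned by mouse embryonic fibroblasts, or for 10 or 32 passages in DC-HAIF, a defined medium whose added factors are heregulin, activin A, an IGF1 analogue and FGF2. The remaining culture was BG03 after 35 passages in MEF-CM. Each culture was represented by 1 array, so no group has replicates and differences between single arrays carry no p-value. Between 11604 and 12202 probes were detected per array, or 24.5% to 25.8% of the probes. The median signal of detected probes lay between 150.7 and 169 intensity units, against a lowest detected signal of 23.6 to 25.2. Of 16790 genes named on the array, 10545 were detected in at least 1 culture and 8263 in all 4.

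The first question was which genes differed between the media in every culture. LEFTY1 and LEFTY2, secreted inhibitors of Nodal signalling, and NODAL itself were lower in both DC-HAIF cultures than in both MEF-CM cultures. LEFTY1 had a normalized signal of 10186 in BG02 and 14515 in BG03 in MEF-CM, and of 1503 at p10 and 735 at p32 in DC-HAIF, a difference of medium means of -3.51 log2 units. LEFTY2 went from 594 and 1596 in MEF-CM to 154 and 88.7 in DC-HAIF, a difference of -2.89, and NODAL from 313 and 268 to 98.7 and 70.5, a difference of -1.62. TAGLN (-2.99), MYL9 (-2.07), FLNC (at least 1.81-fold) and ACTG2, a smooth muscle actin, were also lower in DC-HAIF. ACTG2 was not detected in DC-HAIF and stood at 43.85 in BG02 and 1248.5 in BG03 in MEF-CM (at least 6.94-fold over the 2 arrays). Other lower genes were FOXQ1 (at least 3.36-fold), ODC1, the first enzyme of polyamine synthesis (-2.36), HNMT (at least 2.19-fold), RGL1 (at least 2.11-fold), IER3 (-1.74) and BGN (at least 1.70-fold). In the other direction, DPPA5, a gene of pluripotent cells, was higher in DC-HAIF, with signals of 280 and 293 against 106 in BG02 in MEF-CM, and was not detected in BG03. PGGHG (238 and 381 against 76.4) and ALOX5 (137 and 111 against 43.4) were not detected in BG03 either. ECEL1 (2.16), PRRT2 (2.12), ZNF417 (1.95), CACNA2D2 (1.77), PMEL (1.72), DPEP3 (at least 3.65-fold), QNG1 (at least 1.53-fold), TCL1A (at least 1.49-fold) and VIPR2 (at least 1.48-fold) were also higher. In all, 68 genes had at least a 2-fold gap between the lower array of the brighter medium and the higher array of the dimmer one, 41 higher and 27 lower in DC-HAIF (60.3% higher, against 72.9% after scaling by medians and 73.4% on the signals as deposited). The other 2 ways of dividing the 4 arrays into pairs gave 7 and 19 genes. With limma on 2 arrays per medium, 0 of 9192 genes passed an adjusted p of 0.05, the smallest adjusted p was 0.137, and 1041 genes had an unadjusted p under 0.05 where 460 would be expected by chance. Medium is partly tied to line and to passage number in these cultures, since no BG03 culture was in DC-HAIF.

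**Figure D1:**
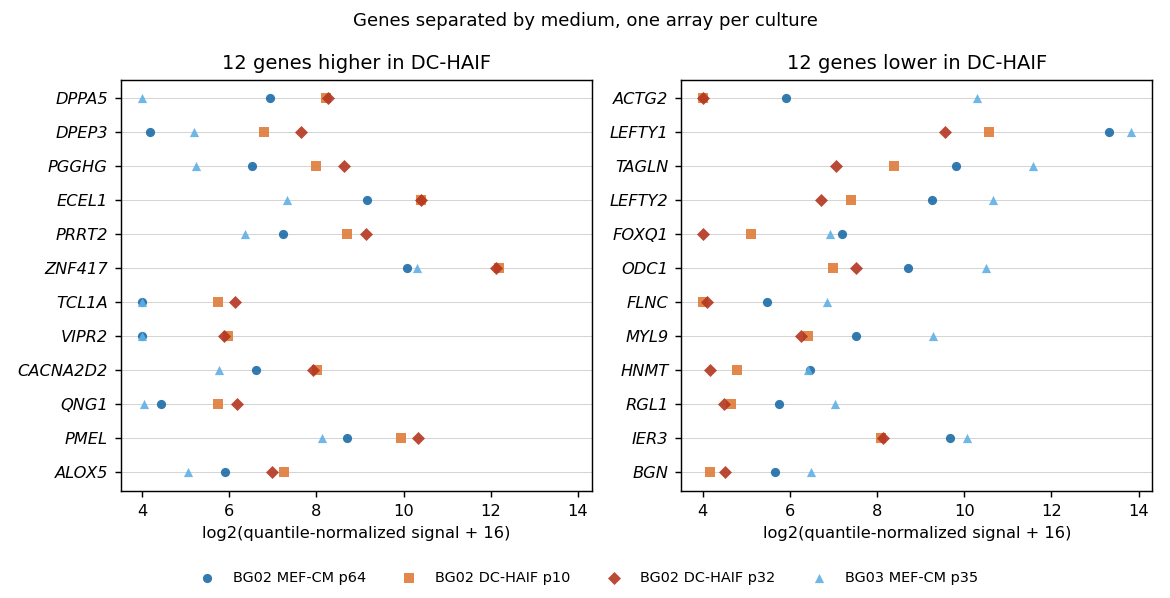
Quantile-normalized signals, as log2(signal + 16), of the 12 genes with the largest difference in each direction among the 68 genes separated by medium; each point is 1 array and signals below 0 are drawn at 0. LEFTY1 stood at 10186 and 14515 in the MEF-CM arrays and at 1503 and 735 in the DC-HAIF arrays.

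Gene lists fixed in advance placed these genes in context. Of 27 lists, 12 had a median difference between the media outside the central 95 percent of 10000 random lists matched on expression. For lists of independent genes, 1.35 would be expected. Single pairs of arrays gave 7 to 11 such lists, with 8 for p32 against p10 in DC-HAIF and 10 for BG02 against BG03 in MEF-CM. Genes of a list can vary together, and some are in over 1 list, so the count of 12 does not by itself show an effect of medium. The list of Nodal and activin targets had a median of -0.98 over 17 detected genes, below all random lists, with 16 members lower in DC-HAIF on average and 4 past the size rule (LEFTY1, LEFTY2, NODAL and TAGLN). The fibroblast and mesenchyme list had a median of -0.89 over 18 genes, also below all random lists, with VIM at -1.82 and COL5A2 at -1.48. These 2 lists were the only ones on the same side of the central range in all 4 pairings of a DC-HAIF with a MEF-CM array. The FGF-ERK list had a median of -0.33 over 20 genes, 14 lower and 6 higher in DC-HAIF. Its members IER3, CCND1 and EGR1 were at -1.74, 0.85 and 0.84. The BMP list had a median of -0.37 over 13 genes, with SMAD7 at -1.21, BAMBI at -0.72 and ID2 at 0.84. The neuroectoderm list had a median of -0.40 over 10 genes, 8 lower and 2 higher. Its member SIX3, not detected in BG03, was at 2.14. These lists lay below the central range, as did the amino acid response (-0.46 over 26 genes), endoderm (-0.57 over 10 genes), NRF2 antioxidant (-0.35 over 20 genes) and interferon lists (-0.29 over 17 genes). The list of receptors for the factors added to DC-HAIF, which also holds the adaptors IRS1 and IRS2, lay above it (0.29 over 12 genes). FGFR3 was past the size rule at 1.21, with signals of 1412 and 1439 against 585 and 634. Within BG02 this list had medians of 0.08 at p10, within the central range, and 0.34 at p32, above it. By medium, cholesterol synthesis genes (0.25 over 24 genes) and hypoxia genes (0.28 over 20 genes) also lay above the central range. Several of these medians changed by over 1.5-fold when an array was left out. Without the BG03 array they were -0.35 for Nodal and activin targets, -0.25 for the fibroblast, -0.08 for the endoderm and -0.01 for the neuroectoderm list, -0.17 for FGF-ERK targets, -0.25 for the amino acid response, -0.16 for NRF2, 0.01 for cholesterol synthesis and -0.04 for hypoxia, and without the p32 array they were -0.63 for Nodal and activin targets, -0.12 for BMP targets, -0.08 for FGF-ERK targets, -0.12 for interferon, -0.36 for endoderm, -0.22 for NRF2 and 0.08 for hypoxia. Without the p10 array they were -0.52 for FGF-ERK targets, -0.17 for interferon, 0.43 for the receptors, 0.13 for cholesterol synthesis and 0.47 for hypoxia, and without the BG02 MEF-CM array -0.88 for endoderm, -1.59 for fibroblast, 0.61 for cholesterol synthesis and 0.73 for hypoxia. The interferon median was -0.18 after scaling by medians. With an offset of 50 it was -0.19, the endoderm median -0.34 and the hypoxia median 0.13, and over members detected in all 4 arrays the endoderm median was -0.27.

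The pluripotency list, which does not hold DPPA5, had a median difference between the media within the central range (-0.01 over 24 detected members). On average 11 members were higher and 13 lower in DC-HAIF, and none was among the 68 genes. LIN28A had signals of 5609 in BG02 and 4582 in BG03 in MEF-CM, and 4582 and 5073 in DC-HAIF. CRIPTO (TDGF1), a Nodal co-receptor, had 8761, 8615, 9028 and 8133 in the same order, and POU5F1 had 418, 207, 290 and 260. DNMT3B differed by -0.01 on its brightest probe, while its other probes gave 1.17 and 0.88. NANOG had 211 in BG02 and 120 in BG03 in MEF-CM and 62.7 and 93.8 in DC-HAIF, a difference of medium means of -0.92, and within BG02 it was lower past the size rule at both passages, by -1.53 at p10 and -1.05 at p32. The SOX2 probe was not detected in any array. UTF1, another member, stood at 343 in BG03 and at 2873, 3016 and 2865 in the BG02 cultures.

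Within BG02, each DC-HAIF culture was then set against the MEF-CM culture. At p10, LEFTY1 was lower by -2.75 log2 units, LEFTY2 by -1.84 and NODAL by -1.52, and at p32 these values were -3.76, -2.54 and -1.93. EOMES and GSC, transcription factors of the primitive streak, were at -1.33 and -1.43 at p10 and at -1.71 and -1.47 at p32, and the primitive streak and mesoderm list had medians of -0.67 and -0.68 over 13 genes (-0.41 and -0.30 with an offset of 50, and -1.12 at p32 over members detected in all 4 arrays). The Nodal and activin list had medians of -0.27 at p10, which was -0.85 over members detected in all 4 arrays, and -0.60 at p32. The fibroblast list had a median of -0.29 at both passages, which at p32 was -0.19 with an offset of 50, -0.14 after scaling by medians and -0.05 on the signals as deposited. The BMP target list had medians of -0.53 and -0.51 over 13 genes and the heat shock list 0.19 and 0.19 over 13 genes, each outside the central range at both passages. The same BG02 array in MEF-CM is the control at both. Against BG03 in MEF-CM both lists lay within the central range. At p10 and p32 the percentiles were 39.2 and 17.7 for BMP targets and 48.3 and 21.5 for heat shock. FGF-ERK targets had a median of -0.46 over 20 genes at p32, below all random lists, and -0.05 at p10. Of them, 15 were lower and 5 higher at p32, and 12 lower and 8 higher at p10. EGR1 was among the higher, at 118.9 at p10 and 70.25 at p32 against 20.4 in MEF-CM, below the lowest detected signal there. On the signals as deposited the p32 medians were -0.27 for BMP targets, 0.34 for heat shock and -0.29 for FGF-ERK targets. At p10, 364 genes were higher and 197 lower than in MEF-CM, and at p32 332 were higher and 196 lower. The share that was higher depended on the scaling: it was 64.9% at p10 and 62.9% at p32, against 75.1% and 75.8% after scaling by medians and 76.0% and 82.6% on the signals as deposited, where the median of all genes at p32 stood at 0.14 against -0.06. Both passages shared 235 genes in the same direction (166 higher, 69 lower), where unchanged arrays simulated against the same control shared 36.95 on average and independent lists would share 11.5 higher and 3.66 lower. With BG03 as the second control, p10 against BG02 and p32 against BG03 shared 108 genes (62 higher, 46 lower), where unchanged arrays shared 5.93 and independent lists 28.9 higher and 16 lower, and the other pairing shared 148 (90 higher, 58 lower), where these values were 5.62, 23.1 and 13.4. The single MEF-CM array serves both comparisons, so part of the shared count may come from that array. All simulated arrays had the spread of p32 against p10 (SD 0.31). The differences of p10 and p32 from BG02 in MEF-CM had SDs of 0.42 and 0.43, and those from BG03 0.64 and 0.69. The simulated counts may thus be too low for unchanged cultures.

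**Figure D2:**
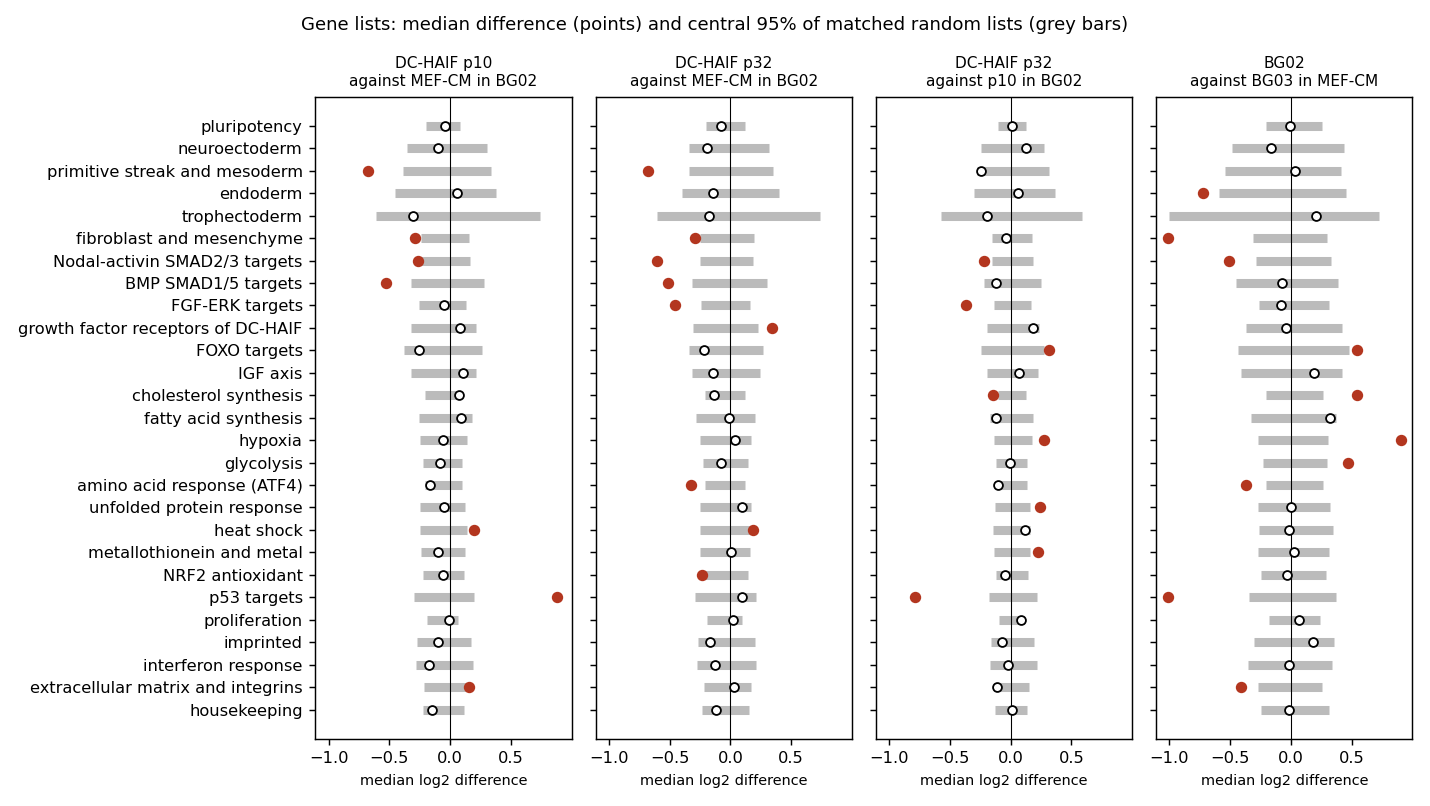
Median log2 difference of the detected members of each of 27 gene lists in 4 comparisons of single arrays, with grey bars for the central 95 percent of 10000 random lists matched on expression and filled points for medians outside it. The Nodal and activin list lies left of its bar in all 4 panels, and the p53 target list lies at 0.88, 0.09, -0.78 and -1.01 from left to right.

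Between the p10 and p32 cultures in DC-HAIF, the list with the largest median difference was that of targets of p53, the transcription factor of the DNA damage response. CDKN1A, a cell cycle inhibitor, had a signal of 694 at p10 and 30.1 at p32, a difference of -3.95 log2 units, and stood at 18.8 in BG02 and 306 in BG03 in MEF-CM. GDF15 (at least 3.60-fold) and PHLDA3 (at least 2.42-fold) were also lower at p32. Of 17 detected members of the p53 list, 16 were lower at p32 than at p10, 7 of them past the size rule, and the median of -0.78 lay below all random lists. Against BG02 in MEF-CM the same list had a median of 0.88 at p10, above all random lists, with 8 members past the size rule (0.49 over members detected in all 4 arrays), and of 0.09 at p32, within the central range. Of the other genes lower at p32, BBS9 had a difference of -2.58, and DENND1C (at least 1.78-fold), PLK2 (at least 1.91-fold), NRDE2 (at least 1.68-fold) and AP5B1 (at least 1.58-fold) were not detected at p32. Higher at p32 were CHCHD2 (5.66-fold), ZIC1 (1.85), and, not detected at p10, MDFI (at least 3.04-fold), MSI2 (at least 3.60-fold), LRRC70 (at least 1.56-fold), NAT16 (at least 1.49-fold), CRNDE (at least 1.37-fold) and PCDH7 (at least 1.87-fold). Another probe of MSI2 gave -0.03 log2 units, and other probes of PCDH7 gave -0.04 and 1.18. ZIC1 stood at 47.2 at p10 and 212 at p32 against 963 in BG02 in MEF-CM, and CHCHD2 at 140 at p10 against 868 at p32, 1042 in BG02 and 6022 in BG03 in MEF-CM. FGF-ERK targets had a median of -0.37 over 20 genes, with 18 lower at p32, and Nodal and activin targets (-0.22 over 17 genes, -0.10 on the signals as deposited) were below the central range too. Medians of FOXO targets (0.32 over 10 genes, 0.21 with an offset of 50), hypoxia (0.27), unfolded protein response (0.24) and metallothionein genes (0.23) were above it. Cholesterol synthesis genes had a median of -0.15, which was -0.08 after scaling by medians and 0.03 on the signals as deposited, where FGF-ERK targets were at -0.20, the unfolded protein response at 0.39 and metallothionein genes at 0.42. In all, 122 genes were higher and 128 lower at p32, 48.8% higher, against 48.7% after scaling by medians and 59.6% on the signals as deposited, where the median of all genes stood at 0.18 against 0.01. Over 8263 genes the SD of the log2 differences was 0.31, the narrowest of the 6 pairs of arrays.

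**Figure D3:**
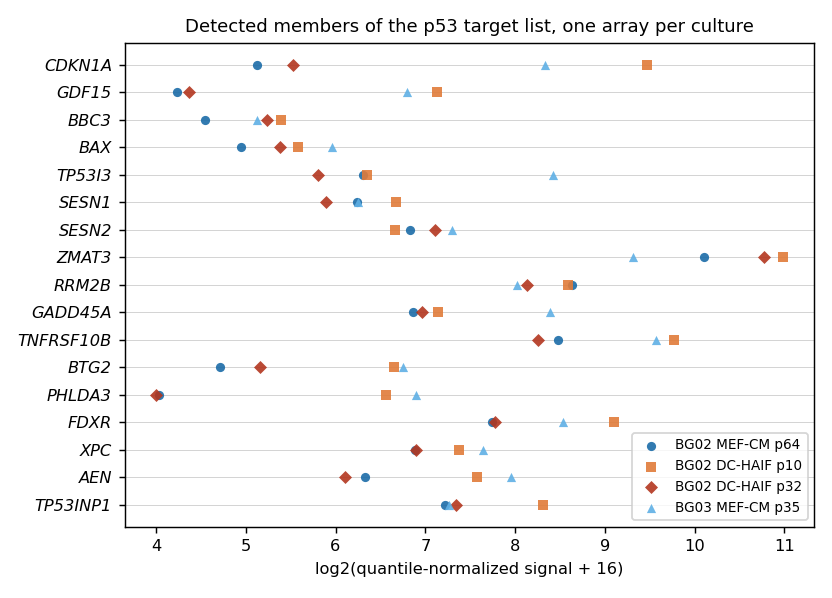
Quantile-normalized signals, as log2(signal + 16), of the 17 detected members of the p53 target list, each point 1 array. CDKN1A stood at 694 at p10 and 306 in BG03, and at 30.1 at p32 and 18.8 in BG02 in MEF-CM.

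The BG02 and BG03 cultures were compared in MEF-CM, and differed in more genes than the media did within BG02. That comparison sets 1 BG02 array, after 64 passages in MEF-CM, against 1 BG03 array after 35. Line thus cannot be told apart from passage number or from the state of a single culture. BG02 had higher signals of PRAC1, a gene of prostate and distal colon (at least 27.3-fold), the transcription factors ZIC1 (at least 24.3-fold), SP8 (3.90) and FOXC1 (at least 6.43-fold), and ATP1B2 (at least 11-fold), CRYZ (at least 9.81-fold) and PTH1R (3.51). ZIC1 also differed within BG02, where it was lower in DC-HAIF by -3.95 at p10 and -2.10 at p32. BG03 had higher signals of AFP, a product of yolk sac and fetal liver (at least 20.2-fold), of the muscle actins ACTC1 (-4.43) and ACTG2 (-4.40), and of NLRP2 (-4.46), NPPB (at least 8.86-fold), ANXA1 (-3.72) and the amino acid transporter SLC7A5 (-3.70). AFP had a signal of 828 in BG03 and was not detected in any BG02 culture. Hypoxia genes were higher in BG02 (median 0.90 over 20 genes, 10 past the size rule higher and 3 lower), with BNIP3 at 3637 against 619. Cholesterol synthesis (0.55 over 24 genes), glycolysis (0.47 over 16 genes) and FOXO target genes (0.54 over 10 genes) were above the central range too, though cholesterol synthesis was at 0.29 and glycolysis at 0.22 on the signals as deposited. The p53 (-1.01 over 17 genes), fibroblast and mesenchyme (-1.01 over 18 genes), endoderm (-0.72 over 10 genes), Nodal and activin (-0.51 over 17 genes), extracellular matrix (-0.41 over 23 genes) and amino acid response lists (-0.37 over 26 genes) were below it. The amino acid response median was -0.62 on the signals as deposited, and over members detected in all 4 arrays the medians were -0.67 for fibroblast, -0.43 for endoderm, -0.31 for Nodal and activin and 0.16 for FOXO target genes. In all, 656 genes were higher in BG02 and 686 lower, 48.9% higher, against 45.4% after scaling by medians and 31.2% on the signals as deposited, where the median of all genes stood at -0.20 against 0.02. The SD of the log2 differences over 8263 genes was 0.60, against 0.42 and 0.43 between media within BG02.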

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

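All tests of this part except that of a shared source of signal were chosen after the result was seen, and 2 of the p53 tests replaced earlier versions. Signal appeared in probes outside the named genes: of 28094 unnamed probes, 48 passed the size rule between the media, 46 higher and 2 lower in DC-HAIF, against at most 5 in the other divisions of the arrays, and 1339 were detected in all 4 arrays.

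LEFTY1, LEFTY2 and NODAL were lower in both DC-HAIF cultures although that medium contains activin A, a ligand of the same pathway. The tables argue against scaling of the arrays as the cause, since the smallest gap between the media over the 3 genes and 3 scalings was -1.31 log2 units. A loss of the stem cell population would lower pluripotency genes with them, but the lower of the 2 medians of that list within BG02 was -0.075, within the central range of random lists, against a median of -1.84 at p10 and -2.54 at p32 over the 3 genes, although NANOG was lower past the size rule at both passages (-1.53 and -1.05) and GAL at p32 (-1.40), and DPPA2, at 77.45 in MEF-CM, was not detected at p10. In limma on 2 arrays per medium, the adjusted p was 0.146 for LEFTY1 and 0.233 for LEFTY2 and NODAL, so none was called, while with line as a further term all 3 were called (adjusted p = 0.0150, 0.0272 and 0.0339), in a fit that sets 2 DC-HAIF arrays against a single MEF-CM array of unmeasured spread. Medium, passage number and differences between cultures stay open and untested as causes.

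The p53 targets were high in the p10 and BG03 arrays and low in the other 2. An exchange of those 2 labels would leave both arrays high, and it would place p32, a BG02 culture, nearer to the array labelled BG03 in most of the 1457 genes that differ between the 2 arrays, but 11.2% were (163 genes, Wilson interval 9.67% to 12.9%). Genes are not independent replicates, so that interval does not measure the spread between arrays or cultures. BG03 cells mixed into the p10 culture would bring their abundant transcripts. But over 15 genes at least 3 log2 units higher in BG03 than in BG02 in MEF-CM, the median share of BG03 signal at p10 was 1.69% (quartiles 0% and 4.6%). The p53 list was left out of these genes. The share was 83.2% (quartiles 53.2% and 126.6%) over 8 p53 targets at least 1 log2 unit higher in BG03 than at p32. That list was singled out for being high at p10, so a large share there follows partly from the choice. A general stress of the p10 culture would raise the other stress lists, but against p32 the amino acid response list was at percentile 96.95, heat shock at 7.47 and the unfolded protein response at 0.17, and the p53 median stayed at -0.75 and -0.67 for p32 against p10 under the other scalings. Against BG02 in MEF-CM, heat shock was above the central range at p10 (percentile 99.2) and at p32 (97.7). The amino acid and unfolded protein response lists were within it at p10 (8.26 and 57.9). The label test replaced 2 that asked whether p10 lay nearer to BG03 (20.3% of 1342 genes), which an exchange does not predict, and the mixing test replaced one that left it open (a median log2 difference of 0.70 with quartiles of 0 and 1.07 over the 15 genes), so what raised the p53 targets at p10 stays open.

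With line as a further term, limma called 87 genes higher in DC-HAIF within BG02 (median 1.37, quartiles 1.20 and 1.53), but that fit sets 2 arrays against the single BG02 array in MEF-CM, so any gene low on that array alone may be among them, and 85 of the 87 were also above BG03 (median 0.86). For a shared source of signal across their probes, the interquartile range of BG02 against BG03 in MEF-CM over the 82 genes detected in all 4 arrays was 0.722 times that of matched random genes, between the bounds of 0.5 and 0.8 set before it was computed, and 1.67% of random sets were as narrow. The genes were chosen on the BG02 array of that difference too, which can narrow it, so a shared source cannot be told apart from separate regulation. The tables argue against scaling as the cause, since the median difference was at least 1.02 times its size under 2 other scalings. The genes called higher were bright, with a median signal of 798 in BG02 in MEF-CM, against 244 over all genes detected in all 4 arrays. Probe sequences, which could show repeats in common, were not used here, and no biological explanation was tested. Genes named in other paragraphs are among the 87: FGFR3, ZNF417, ECEL1, PRRT2, PMEL, DPEP3, HSD17B7, AHR, LAMA5 and SLC7A11. The same limits hold for them.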

How the results depend on the processing

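Of the values for single genes under the alternatives, 1608 stayed within the limits set for them, 176 moved, 84 came to pass the threshold and 97 no longer did. Part of the 1608 was fixed in advance. Other folds and detection filters leave the difference of a gene as it was, and the value table of the series repeats the deposited signals. Of the list medians, 217 stayed, 58 moved and 3 changed sign. Counts are given in the order of the media, p10 against MEF-CM, p32 against MEF-CM, p32 against p10, and BG02 against BG03. With an offset of 50 they were 27, 195, 173, 33 and 587, and with detection in all 4 arrays 39, 270, 260, 54 and 724. At 1.5-fold they were 403, 1806, 1910, 1094 and 3292, and at 3-fold 9, 87, 68, 26 and 386. With every probe counted by itself, the first 4 were 116, 1080, 1005 and 436, and without a detection filter p32 against p10 gave 436. The changes at other folds follow from the looser or stricter threshold. Lower counts with an offset of 50 or detection in all 4 arrays place much of each count among genes weak or undetected in some array. Counting every probe adds unnamed and second probes, and 48 unnamed probes passed between the media. With 1 array left out, the medium count ranged from 213 to 1011, since fewer arrays must then separate: 1011 without BG02 in MEF-CM, 213 without p10, 216 without p32 and 235 without BG03. Each count held all 68 genes, which was fixed in advance, since a gene that separates 4 arrays also separates those that remain. The limma count of 0 ranged from 0 to 1004 with an array left out (1004 without BG02 in MEF-CM, 1 without p10, 116 without BG03), where the lone array is assumed to vary like the others. It was 1 on the signals as deposited, 1 on the value table of the series, and 96 with line as a further term. The cholesterol list for p32 against p10 turned to 0.0263 on the signals as deposited and on the value table, and the hypoxia list by medium to -0.0376 without BG03 (up to 0.726 with other arrays left out); the cause was not tested. No paired analysis was possible because each group has 1 array. No slide is named in the tables, so slide as a block was not run. The lowest detected signal of 23.6 to 25.2 limits folds of weak genes.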

Other observations

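The test of gene density and that of the division of the arrays were chosen after the result was seen. Some genes that separated BG02 in DC-HAIF from BG02 in MEF-CM did not separate all 4 arrays by medium. With line as a further term, limma called 96 genes, 87 higher and 9 lower in DC-HAIF, 24 of them among the 68 genes above. That fit has residual degrees of freedom of 1: 2 DC-HAIF arrays are set against a single BG02 array in MEF-CM, whose own spread was not measured. Among those higher were AHR, the receptor for aryl hydrocarbons (1.41, SE 0.12, adjusted p = 0.0116), LAMA5, a laminin chain, and SLC7A11, a cystine transporter, with signals of 2755 and 2608 against 1018 for LAMA5 and of 8133 and 7832 against 3535 for SLC7A11. In BG03 in MEF-CM these 2 genes stood at 1897 and 5424. AHR, LAMA5 and SLC7A11 were chosen after their values were seen. A shared source of signal across the probes of the genes called higher could not be told apart from separate regulation.

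Some genes passed the size rule within BG02 at both passages while the median of their list lay within the central range. SREBF1, a transcription factor of fatty acid synthesis, had signals of 280 and 256 in DC-HAIF against 97.8 in BG02 and 131 in BG03 in MEF-CM. HSD17B7, an enzyme of cholesterol synthesis, had 1977 and 1624 against 722 and 978. The imprinted gene NNAT had 219 and 279 against 86.5 and 54.1, with another probe at 0.41 log2 units.

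The division of the 4 arrays by medium gave 68 genes and the highest other division 19, so 1 of the 3 divisions gave as many; 3 divisions are too few for a share under 0.05.

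Before the data were examined, it was proposed that less lipid in the defined medium could raise cholesterol synthesis genes. Their list was at percentile 99.87 by medium, at 96.4 within BG02 at p10 and at 15.1 at p32. Its medians within BG02 were 0.07 at p10 and -0.13 at p32, both within the central range. Against BG03 they were 0.70 and 0.46, and the list was higher in BG02 than in BG03 within MEF-CM (0.55). The difference by medium thus rested on the BG03 array, and no rise outside the central range was seen within BG02. Each culture has 1 array, so a smaller rise cannot be excluded.

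It was also proposed that the DC-HAIF cultures could hold a different share of differentiated cells. Of the 5 lineage lists, 3 lay outside the central range by medium, all below it (neuroectoderm, endoderm and fibroblast), while the primitive streak and mesoderm list was at percentile 2.82 and trophectoderm at 23.5. Within BG02, the primitive streak and mesoderm list (-0.67 at p10, -0.68 at p32) lay below the central range at both passages. So did the fibroblast list (-0.29 at both, but -0.05 at p32 on the signals as deposited). The BG03 culture cannot produce this, but the single BG02 array in MEF-CM, the control at both passages, could. Against BG03 in MEF-CM, the fibroblast list lay below all random lists at both passages. The primitive streak and mesoderm list was there at percentile 0.05 at p10 and 19 at p32, the latter within the central range. Within BG02, the endoderm (0.05 and -0.14), neuroectoderm (-0.10 and -0.19) and trophectoderm lists (-0.31 and -0.17) lay within the central range. BG03 had AFP at 828 and ACTC1 at 3156. A lower share of differentiated cells in DC-HAIF cannot be told apart from an effect on the genes of these lists.

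A gain or loss of a whole autosome was looked for in the median difference of each of 22 autosomes. The largest shift was 0.28 for chromosome 19 between DC-HAIF p32 and BG03, and the largest between BG02 arrays was 0.117. Chromosome 19 lay outside the range of random gene sets of its size in all 6 pairs of arrays, chromosomes 4 (-0.14 and -0.19) and 16 (0.13 and 0.19) in 2 pairs each with BG03, chromosome 13 (-0.21) in 1 with BG03 and chromosome 5 (-0.09) for p32 against BG02 in MEF-CM. The shifts followed gene density of the chromosome, with Spearman's rho of at least 0.715 across autosomes between BG02 and BG03 arrays (the permutation p was 0.0009 for that pair, adjusted p = 0.00108 over 6 pairs of arrays) and of 0.570, 0.773 and 0.857 between BG02 arrays (adjusted p of 0.0060 or lower), which is consistent with a trend across the genome. Autosomes are not independent replicates, and a copy number change of any of these chromosomes cannot be told apart from that trend here.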
